A study of Bos taurus with 87 samples.

How the data were processed

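Polyadenylated RNA of cattle (Bos taurus) was sequenced from the tissues that form the placenta, on the side of the conceptus and on the side of the mother. Pregnancies were begun by artificial insemination (AI) or by somatic cell nuclear transfer (SCNT, the cloning method in which the nucleus of a body cell is placed in an egg). Per the labels' protocols, RNA came from snap-frozen tissue by phenol-chloroform extraction with TRIzol, a further acid phenol step and column purification, and was assayed on a Bioanalyzer before polyA+ library construction.

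The deposited values were whole-number read counts per gene, 1 column per library, in 2 tables made by the authors, for the conceptus and for the endometrium, with the exon length of each gene beside them. CASAVA 1.8.2, TopHat and Picard were used, per the submitters' processing notes, which give no role or order. The genome build, the gene annotation, the counting program and whether it used the strand are not given in the sources used here. Counts were used as deposited, and both tables held only columns that matched a sample. Total counts ranged from 4224603 to 9223101 in the 35 conceptus libraries and from 4942869 to 13625388 in the 52 endometrium libraries. No pair of libraries of a group agreed within sampling noise, since the smallest chi-square per degree of freedom between members of a group was 5.39. The labels do not say which libraries came from the same animal, so p-values measure the spread between libraries.

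Gene names were available for few genes. The conceptus table held 19037 identifiers, of which 309 (1.62%, with 1.4% of the counts) were Entrez identifiers that a RefSeq table of symbols named. The endometrium table held 19511, of which 313 (1.6%, with 1.44% of the counts) were named. The remaining identifiers were almost all Ensembl identifiers, which the sources used here do not pair with symbols, so those genes were counted and tested but not named. Some identifiers carried counts identical to those of another identifier in every library. With a total of at least 100 counts there were 37 in the conceptus table and 36 in the endometrium table, with 14 and 13 named genes among them. Values of such genes are given as uncertain, because the origin of the identical counts was not tested.

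Groups were formed by tissue, day of gestation and kind of pregnancy. SCNT was compared with AI pregnancies within each of 7 sets, namely day 18 extra-embryonic tissue, day 34 chorion, day 34 allantois, and caruncle and inter-caruncle endometrium at day 18 and at day 34. Differences of the SCNT effect between tissues or days were tested as interaction terms, and tissues and days were compared within AI pregnancies. These 17 comparisons used edgeR 4.0.16 in R 4.3.3, on the libraries of the groups compared only. Genes were kept by filterByExpr (minimum count 10, minimum total 15), library sizes were scaled by the trimmed mean of M values (TMM), and the robust quasi-likelihood F-test was applied with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values below come from this test unless another is named. By chance alone between 611 and 767 genes of a comparison would have an unadjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Mean CPM values and their standard deviations use the TMM-scaled library sizes. Values of XIST, H19 and TKDP1 for single libraries use the plain total unless TMM-scaled sizes are named.

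Genes were named by a rule fixed before the data were examined. It takes genes with an adjusted p under 0.05, a symbol, at least 5 CPM in the higher group and no overlap between the groups' libraries, up to 10 in each direction. Where no gene passed, the rule takes the 5 named genes with the smallest p, as values. It also takes the 2 to 4 members with the smallest p of each gene list described, and a short set of placental and endometrial genes, of which H19 and XIST were named here. For interactions and comparisons within AI pregnancies it takes the 5 higher and 5 lower named genes with the smallest p. Beyond the rule, 4 genes without a symbol were named after their values were seen. Of 37 gene lists with 1671 symbols fixed beforehand, 22 symbols were named in the conceptus table and 23 in the endometrium table, and 1 list, imprinted genes, had at least 3 named members. Another 11 lists were assembled from the named genes after their names and mean counts had been seen and before any fold change was computed. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists of a comparison. Members are counted over all genes tested and, in those words, adjusted over the list alone.

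The spread within groups was measured as the mean distance between libraries on log2 CPM (prior count 2). The permutation planned for it was tested on simulated data of equal spread, where it gave p under 0.05 in 79% of 200 draws with 5 against 9 libraries, when genes varied independently. It was replaced, after that simulation, by a permutation of each library's distance to its group mean, which gave 7.5% in the same draws. When 1 factor was shared by all genes the planned permutation gave 12% and its replacement 11.5%, so that the p-values of both are too small. Overlaps of calls between tissues were tested with Fisher's exact test, one-sided, per direction.

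The main test was checked on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes taken from the more abundant ones. Genes were drawn independently, so that the rates do not cover factors shared between genes. The share of genes changed, on which the adjustment depends, was small. In day 18 extra-embryonic tissue it was 200 of 12117, where 5619 of 12223 real genes passed. The rates therefore do not describe sets in which many genes passed. For day 18 extra-embryonic tissue the test called 24% of genes changed 2-fold, 86% of those changed 4-fold and 100% of those changed 8-fold, with 5 false calls among 110. Day 18 caruncle gave 92% of genes changed 2-fold, and day 34 caruncle 14%.

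Alternatives were the size factors of DESeq2 1.42.0 (RLE) or none in place of TMM, no filter or a filter at 1 CPM, the DESeq2 Wald test, limma-voom with sample quality weights, a further threshold of 2-fold, 1 surrogate variable from sva 3.50.0, log2 CPM of XIST as a covariate in the conceptus, a block for title numbers, and each library left out in turn. Chosen after seeing the data were the removal of each library's trend on exon length, keeping identifiers with identical counts once, leaving out the library of each group farthest from its mean, and runs without scaling or with limma-voom for interactions and comparisons within AI pregnancies. The caruncle library with title number n and the inter-caruncle library with the following number were taken as a candidate pair. At day 18 the deviations of the 2 members of a pair from their group means correlated in all 14 pairs, with r from 0.16 to 0.69, and 12 of the 14 caruncle libraries correlated best with their own partner, so that the numbers were treated as pairing the samples. The pairing comes from the titles alone.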

Results

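Gene expression was compared between SCNT and AI pregnancies of cattle in 87 libraries of 14 groups. Extra-embryonic tissue, the membranes of the elongating conceptus, was sampled at day 18 of gestation and represented by 5 AI and 9 SCNT libraries. At day 34 the chorion, the outer membrane that meets the uterus, was represented by 5 AI and 7 SCNT libraries, and the allantois, the inner sac that carries the fetal vessels, by 4 and 5. Endometrium, the lining of the uterus, was taken from the caruncles, the aglandular sites where the placenta attaches, and from the inter-caruncular area, which holds the glands. Each was represented by 5 AI and 9 SCNT libraries at day 18 and by 5 AI and 7 SCNT libraries at day 34. Total counts lay between 4224603 and 9223101 per conceptus library and between 4942869 and 13625388 per endometrium library. The question of the series concerns genes of cell signalling and placental development in cloned pregnancies, on the side of the conceptus and of the mother.

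XIST (Entrez Gene 338325), the RNA that coats and silences an X chromosome in female cells, was higher in SCNT than in AI conceptuses in each of the 3 conceptus tissues. In day 18 extra-embryonic tissue it averaged 12.1 CPM (SD 14.9, n = 5) in AI and 450 CPM (SD 250, n = 9) in SCNT libraries, a log2 fold change of 5.24 ± 0.86 (SE, adjusted p = 0.00772). In day 34 chorion the means were 2.55 CPM (SD 2.9, n = 5) and 464 CPM (SD 443, n = 7), a log2 fold change of 7.55 ± 0.999 (adjusted p = 0.00573), and in allantois 1.17 CPM (SD 1.01, n = 4) and 466 CPM (SD 271, n = 5), a log2 fold change of 8.64 ± 0.77 (adjusted p = 0.00101). By plain library totals, the 14 AI conceptus libraries lay between 0 and 29.8 CPM and the 21 SCNT libraries between 57.6 and 1254 CPM. The labels do not give the sex of the conceptuses.

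**Figure D1:**
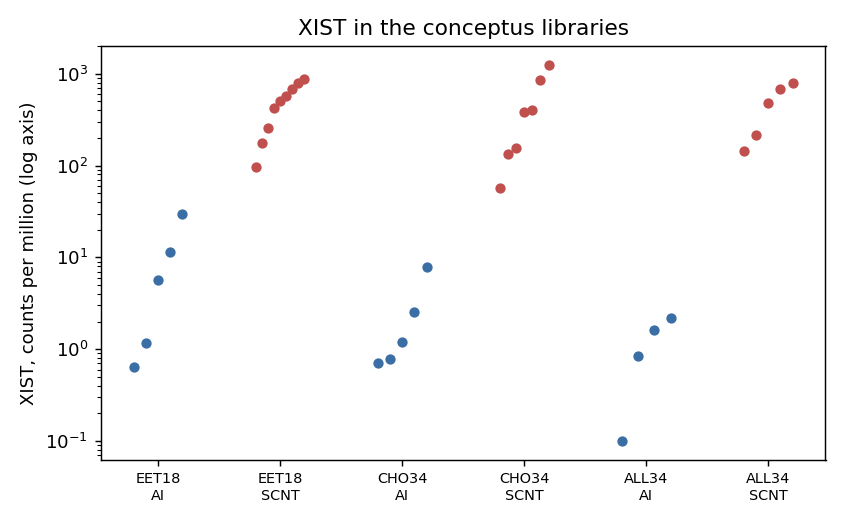
XIST in each conceptus library, in CPM on a log axis (values under 0.1 are drawn at 0.1), for day 18 extra-embryonic tissue (EET18), day 34 chorion (CHO34) and day 34 allantois (ALL34). Each point is 1 library, blue for AI and red for SCNT pregnancies; the highest AI library lies at 29.8 and the lowest SCNT library at 57.6.

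In day 18 extra-embryonic tissue ELAPOR2 was higher in SCNT (0.49 CPM, SD 0.37, against 5.14 CPM, SD 1.71; log2 fold change 3.25 ± 0.49), as was SLC24A4, a sodium/calcium/potassium exchanger (22.6 CPM, SD 6.09, against 42.9 CPM, SD 5; 0.92 ± 0.22). AURKC, a kinase of meiosis and early cleavage divisions, fell from 17.4 CPM (SD 8.5) to 2.20 CPM (SD 1.24), a log2 fold change of -2.96 ± 0.41 (adjusted p = 0.00332). PLXNA3, a semaphorin receptor, fell from 6.81 CPM (SD 3.31) to 2.36 CPM (SD 0.755), and CKS2, which binds cyclin-dependent kinases, from 146 CPM (SD 41.6) to 96.6 CPM (SD 11.4). FAM174B was at 22 CPM (SD 28.8) in AI and 2.39 CPM (SD 1.13) in SCNT libraries, the AI mean being raised by library 20. The counts of CKS2 and FAM174B were identical to those of a second identifier and are uncertain. The call of CKS2 was lost without scaling (log2 fold change -0.27, adjusted p = 0.171) and without AI library 20 or 9 (adjusted p up to 0.119). H19 (Entrez Gene 100126192), an imprinted RNA expressed from the maternal allele, averaged 151 CPM (SD 27.8) in AI and 84 CPM (SD 44.6) in SCNT libraries. Its log2 fold change of -0.84 ± 0.33 passed narrowly (adjusted p = 0.0489), and did not pass without scaling (-0.55, adjusted p = 0.176), with limma-voom (adjusted p = 0.154) or in 12 of 14 runs with 1 library left out (adjusted p up to 0.106), all but those without AI library 52 or SCNT library 40. Among genes without a symbol, chosen after their values were seen, ENSBTAG00000007778 rose from 0.104 CPM (SD 0.155) to 10.3 CPM (SD 3.37) and ENSBTAG00000021978 fell from 62.6 CPM (SD 71.4) to 1.40 CPM (SD 0.904).

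Named genes of several groups changed in both directions at day 18. These groups were assembled from the named genes before any fold change was seen, and camera called none of the 8 lists (smallest adjusted p = 0.288). Over all genes tested 46% passed, 2148 higher and 3471 lower, the share beside which the counts of members below stand. Of 17 mitochondrial proteins 6 fell, 2 rose and 9 did not pass, the same numbers as adjusted over the list alone. Those that fell included the respiratory chain subunit COX6B1 (190 CPM, SD 72.2, to 99.4 CPM, SD 15.2), the ATP synthase subunit ATP5MJ (98.3 CPM, SD 35, to 55.9 CPM, SD 9.88), the transporter ABCB8 and the quality-control kinase PINK1 (log2 fold changes -0.93, -0.81, -1.52 and -1.30). Without scaling ATP5MJ did not pass (-0.46, adjusted p = 0.0639). Of 9 redox genes 3 fell, 1 rose and 5 did not pass. PGD, an enzyme of the pentose phosphate pathway, fell by 0.92 on the log2 scale, the glutathione peroxidase GPX2 by 2.04 and the methionine sulfoxide reductase MSRA by 0.61, and TXNIP, an inhibitor of thioredoxin whose counts were identical to those of a second identifier, rose by 0.86. MSRA did not pass without scaling (-0.28, adjusted p = 0.219). Of 9 genes of cell division and DNA maintenance 3 fell and 1 rose, with the DNA repair gene FANCE at -1.59 and ZRANB3, which acts at stalled replication forks, at 1.74. Its median and mean were 0.37 and 0.07, while camera gave a downward direction (adjusted p = 0.984). Of 14 genes of the endoplasmic reticulum and Golgi 2 rose (GALNT4, 1.13, and SFT2D2, 0.96) and 2 fell (EMC10, -1.08, and DOLK, -0.99). Of 14 cytoskeleton genes 2 rose, DOCK8 by 1.70 and CHN2 by 0.96, and 4 fell, among them the actin-binding TWF2 (-1.46) and MARCKSL1 (-0.87; -0.50 without scaling, adjusted p = 0.0876), with a median of -0.34, a mean of 0.10 and a downward direction by camera (adjusted p = 0.812). Of 16 zinc finger genes 3 rose (ZNF557, 2.19, and ZNF484, 2.60, among them) and 3 fell (ZNF444, -2.24, and ZNF775, -1.88, among them). Their balance was called upward by fry (adjusted p = 0.0488), but not with RLE scaling (adjusted p = 0.063), with a median log2 fold change of 0.58. Of 4 genes on the leukocyte list NLRP12 and DOCK8 rose (2.22 and 1.70), DOCK8 being the gene counted above among the cytoskeleton genes. MCOLN2 and TNFSF13 did not pass (0.56 and 0.22), MCOLN2 passing with limma-voom (adjusted p = 0.0191). The list was called by fry (adjusted p = 0.000648), which does not compare it with other genes, and not by camera (adjusted p = 0.288; 0.438 with an estimated correlation). Of 3 erythroid genes SMIM1 fell by 1.42, SLC25A37 rose by 0.80, and SMIM5 had a log2 fold change of -0.88 that did not pass over all genes tested but passed adjusted over the list alone and with limma-voom (adjusted p = 0.00732). Without scaling SLC25A37 did not pass (0.96, adjusted p = 0.0562). Which cells carried the transcripts of the leukocyte and erythroid lists was not tested.

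Several of these calls did not pass with 1 library left out. Such runs also changed how many genes passed (821 without AI library 20), which moves every adjusted p. A lost call alone does not show that the effect rested on that library. Without AI library 20 the calls of ZNF484, ZNF775, DOLK, PGD, GPX2, TWF2 and FANCE were lost, with an adjusted p of 0.0567, 0.0728, 0.0632, 0.0507, 0.0634, 0.0525 and 0.0502. ATP5MJ and ZRANB3 were lost without AI library 20 or 9 (adjusted p up to 0.0602 and 0.0581), DOCK8 without AI library 20 or 13 (up to 0.0501), and CHN2 and MARCKSL1 without AI library 20, 9 or 35 (up to 0.0664 and 0.0752). GALNT4, MSRA, SLC25A37 and TXNIP were lost without AI library 20, 9 or 35 or SCNT library 26, 21, 37 or 48 (up to 0.0801, 0.0979, 0.0991 and 0.0731). GALNT4 was lost also without AI library 13, MSRA and SLC25A37 without SCNT library 40, and TXNIP without SCNT library 54 or 39. XIST, ELAPOR2, SLC24A4, FAM174B, AURKC, PLXNA3, COX6B1, PINK1, ABCB8, NLRP12 and SMIM1 passed in all 14 runs.

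By edgeR's test 5619 of 12223 genes (46%) passed in day 18 extra-embryonic tissue, 2148 higher and 3471 lower in SCNT, and 3932 of them changed at least 2-fold. Of 191 named genes tested 28 were higher and 61 lower. The groups did not overlap for 135 genes (1.1%, where chance gives 0.0999%). The count fell to 821 without AI library 20, 2721 without AI library 9, 3622 without AI library 35 and 3741 without SCNT library 48, and to 0 with XIST as a covariate, a measure that separated the groups (7114 genes had an unadjusted p under 0.05 without it, and DESeq2 called 7098 and limma-voom 8295). The count rose to 8375 without AI library 52, and was 3380 without the library of each group farthest from its mean. AI libraries 20, 9 and 35 had TMM factors of 0.666, 0.774 and 0.832, where SCNT libraries lay between 1 and 1.17. The factors of AI libraries 13 and 52 were 1.08 and 1.1. Without scaling 3295 genes passed, 1498 higher and 1797 lower, and the median log2 fold change of all genes moved by 0.25.

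**Figure D2:**
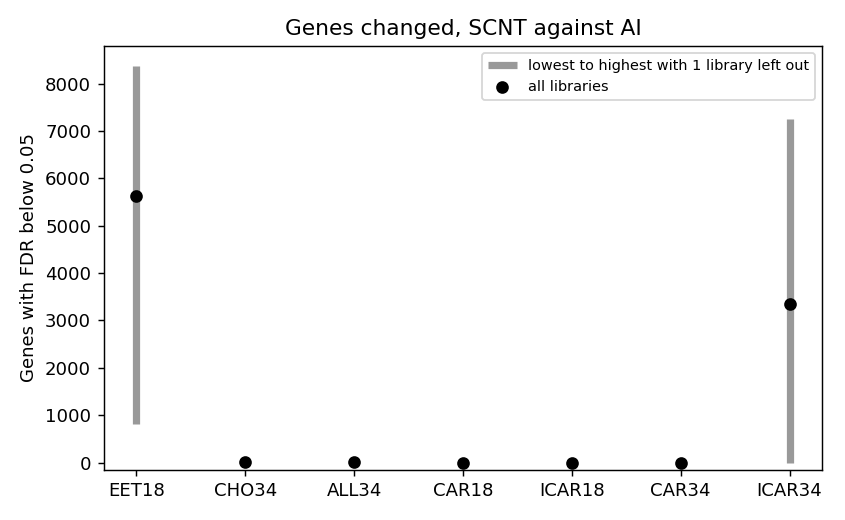
Number of genes with an adjusted p under 0.05 between SCNT and AI pregnancies in each of the 7 sets, with all libraries (black points) and as the range from the lowest to the highest number with 1 library left out (grey bars), on a linear axis. Extra-embryonic tissue at day 18 (EET18) ranges from 821 to 8375 and inter-caruncle endometrium at day 34 (ICAR34) from 0 to 7254; CHO34 is chorion, ALL34 allantois, CAR caruncle and ICAR inter-caruncle endometrium, and the number is the day.

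In day 34 chorion 18 of 12939 genes passed, 11 higher and 7 lower in SCNT, and all 18 changed at least 2-fold. At an unadjusted p under 0.05 there were 490, where chance gives 647. XIST was the only one with a symbol among 197 named genes tested. The genes without a symbol included, chosen after their values were seen, ENSBTAG00000013768, at 0.353 CPM (SD 0.256, n = 5) in AI and 55.3 CPM (SD 6.68, n = 7) in SCNT libraries, and ENSBTAG00000002214, at 38.1 CPM (SD 17.9) and 3.95 CPM (SD 1.45). H19 did not pass (342 CPM, SD 103, against 395 CPM, SD 97.9; log2 fold change 0.21 ± 0.21, adjusted p = 1). The list of imprinted genes was called upward by camera (adjusted p = 0.000195; 0.00359 with an estimated correlation). Of its 4 measured members XIST rose, and RTL1, H19 and MEG3 did not pass, also adjusted over the list alone. XIST acts on a whole chromosome and is imprinted in the extra-embryonic tissue of some species. A second list, of transcripts of imprinted domains without XIST, was called by camera with none of its 5 members passing (adjusted p = 0.0267, and 0.157 with an estimated correlation). The number of genes was 9 without SCNT library 31, 10 without SCNT library 23 and 11 without AI library 29, and 1 with XIST as a covariate. DESeq2 called 71, limma-voom 72 and a fit with 1 surrogate variable 54.

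In day 34 allantois 7 of 13432 genes passed, 5 higher and 2 lower in SCNT, and XIST was again the only named one, among 208 tested. H19 averaged 668 CPM (SD 123, n = 4) in AI and 704 CPM (SD 129, n = 5) in SCNT libraries (log2 fold change 0.08 ± 0.18, adjusted p = 0.92), with a sign that turned without scaling (-0.01). Of the 4 imprinted genes XIST rose and 3 did not pass, also adjusted over the list alone. Camera did not call the list (adjusted p = 0.194), and fry did (adjusted p = 0.0484), but not without scaling (adjusted p = 0.168). The transcripts of imprinted domains had a median of 0.08, a mean of -0.15 and a downward direction by camera (adjusted p = 0.659). The 16 mitochondrial proteins had a median log2 fold change of -0.18 and the 4 erythroid genes of -0.43, with no member passing and an adjusted p of 0.0519 for each list by camera. Of 3 liver and yolk sac genes (CEBPA, FGB and LIPC) none passed, with a median of -0.55 (camera adjusted p = 0.17). The number of genes was 2 without AI library 38, AI library 15 or SCNT library 28, 13 without AI library 12, 87 without SCNT library 18, 4 without the library of each group farthest from its mean, and 0 with XIST as a covariate, where 1589 genes had an unadjusted p under 0.05 without it (chance gives 672). DESeq2 called 231 and limma-voom 12. The SCNT effect differed between chorion and allantois for 1 gene of 14149, without a symbol (710 at an unadjusted p under 0.05, where chance gives 707; DESeq2 17, limma-voom 22). With 1 library left out that number was 0 in 17 of 21 runs, 1 without chorion AI library 8, and 2 without chorion SCNT library 49, allantois AI library 15 or allantois SCNT library 14. Chorion and allantois shared 3 of the genes called higher, XIST among them, where independent lists would share 0.00227 (Fisher's exact test, one-sided, p = 4.47e-10, adjusted p = 1.79e-09 over the 4 overlaps with genes on both lists). Sex of the conceptuses and kind of pregnancy cannot be told apart in either tissue, since XIST separated the groups in both. Extra-embryonic tissue at day 18 shared 3 higher genes with chorion, where independent lists would share 1.42 (Fisher's exact test, one-sided, p = 0.155, adjusted p = 0.31), and 1 with allantois (p = 0.441). At a threshold of 0.01 for the calls both overlaps passed Fisher's exact test, one-sided, with 2 genes shared with chorion (Fisher's exact test, p = 0.000472) and 1 with allantois (Fisher's exact test, p = 0.00978), not adjusted. At either threshold XIST was among the genes shared with chorion and was the only gene shared with allantois. XIST separated the groups in extra-embryonic tissue as well, so that sex and kind of pregnancy cannot be told apart in these overlaps.

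Endometrium at day 18 showed no gene past the threshold in edgeR's test, in caruncle (14884 genes tested) or between caruncles (14874 genes tested). At an unadjusted p under 0.05 there were 1197 and 465 genes, where chance gives 744 in each. DESeq2 called 5 and 1, and limma-voom 0 and 0. In caruncle the named genes with the smallest p were GALNT4, an enzyme of O-linked glycosylation (39.1 CPM, SD 6.08, n = 5, in AI and 49.4 CPM, SD 5.14, n = 9, in SCNT), FAM110B (3.87 and 5.30 CPM), SMIM13 (51.3 and 59.7 CPM), the macrophage gene MPEG1 (138 CPM, SD 41.8, and 105 CPM, SD 14.3) and P4HA1, an enzyme of collagen maturation (64.5 and 80.7 CPM), with adjusted p between 0.573 and 0.606. Between caruncles they were the chemokine CXCL11 (7.80 CPM, SD 2.89, and 3.36 CPM, SD 1.99), C15H11orf96 (24.3 and 36.5 CPM), ZNF703 (7.91 and 12.9 CPM), the fibrinogen gene FGB (3.81 and 2.74 CPM) and RBM20 (3.02 and 2.08 CPM), each with an adjusted p of 0.956. Camera called no list in either area with TMM scaling. The 8 leukocyte genes had a median log2 fold change of -0.38 in caruncle (adjusted p = 0.0621, 0.384 with an estimated correlation, and 0.0492, past the threshold, without scaling) and -0.18 between caruncles (adjusted p = 0.0892, 0.498 with an estimated correlation). The 3 imprinted genes H19, XIST and MEG3 did not pass in either area, also adjusted over the list alone (camera adjusted p = 0.99 and 0.545). In caruncle their median was 0.02 and their mean -0.02, with an upward direction by camera that turned without scaling. The SCNT effect differed between the areas for 0 of 15333 genes (393 at an unadjusted p under 0.05, where chance gives 767, and 0 each by DESeq2 and limma-voom).

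In day 34 caruncle H19 had the smallest p of the named genes, at 204 CPM (SD 61.7, n = 5) in AI and 401 CPM (SD 133, n = 7) in SCNT libraries. Its log2 fold change of 0.98 ± 0.27 did not pass (adjusted p = 0.408). Every SCNT library lay above every AI library. Over all genes tested the groups did not overlap for 104 of 14785 (0.703%, where chance gives 0.253%). The named genes with the next smallest p were ATP5MK, a subunit of ATP synthase (1.71 CPM, SD 0.283, and 4.22 CPM, SD 1.63), SCOC (18.0 CPM, SD 8.89, and 48.8 CPM, SD 22.8), PIN4 (5.52 CPM, SD 1.04, and 2.51 CPM, SD 0.91) and LOC100196897 (2.52 and 0.784 CPM). SCOC passed with DESeq2 (adjusted p = 0.0242), and ATP5MK, SCOC and PIN4 passed with limma-voom (adjusted p = 0.0115, 0.00417 and 0.0449). The 14 genes of the endoplasmic reticulum and Golgi were called upward by camera with no member passing (adjusted p = 0.0118, and 0.401 with an estimated correlation; 1 passed adjusted over the list alone). Of the 3 imprinted genes none passed over all genes and 1 passed adjusted over the list alone (camera adjusted p = 0.101, fry 0.0484, and fry 0.0979 without scaling). No gene of 14785 passed in edgeR's test (1141 at an unadjusted p under 0.05, where chance gives 739), while DESeq2 called 123, limma-voom 601 and a fit with 1 surrogate variable 1309. The number by edgeR was 12 without SCNT library 64 and 2 without SCNT library 68.

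**Figure D3:**
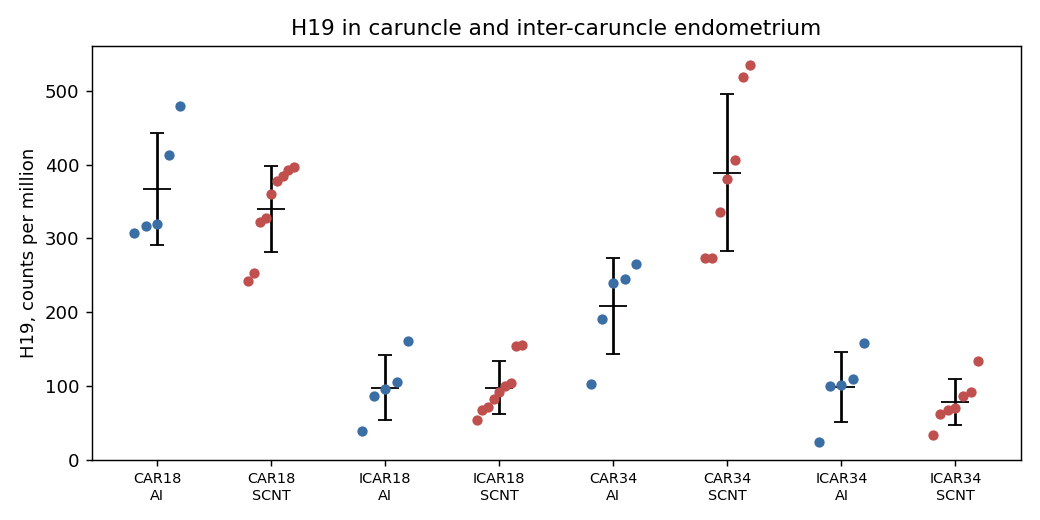
H19 in each endometrium library, in CPM of the plain library total on a linear axis from 0, for caruncle (CAR) and inter-caruncle (ICAR) endometrium at days 18 and 34, AI in blue and SCNT in red. Bars show the mean and SD of each group; the day 34 caruncle means are 209 in AI and 389 in SCNT libraries.

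In day 34 inter-caruncle endometrium the named genes whose groups did not overlap were FAM229B, which rose from 11.2 CPM (SD 1.36, n = 5) to 22.6 CPM (SD 4.99, n = 7; log2 fold change 1.01 ± 0.24), SMIM1, the Vel blood group gene, which fell from 14 CPM (SD 5.95) to 4.35 CPM (SD 1.88; -1.64 ± 0.36), and PLXNA3, which fell from 78.2 CPM (SD 17.8) to 34.3 CPM (SD 14.2; -1.19 ± 0.28). Each had an adjusted p of 0.0424. XIST, here a transcript of the mother, rose from 566 CPM (SD 100) to 1046 CPM (SD 428; 0.89 ± 0.28, adjusted p = 0.0442). Of 14 genes of the endoplasmic reticulum and Golgi 4 rose and none fell, namely ERLIN1 (110 to 207 CPM), GALNT4 (21 to 42 CPM), TMEM167B and SFT2D2. Camera did not call the list (adjusted p = 0.508), and SFT2D2 did not pass with RLE scaling or without scaling (adjusted p = 0.0506 and 0.0526). Of 9 genes of cell division and DNA maintenance the ribonucleotide reductase RRM1 (113 CPM, SD 57.1, to 212 CPM, SD 61.7, with counts identical to those of a second identifier) and ANAPC13 rose and none fell, while adjusted over the list alone 5 rose and 1 fell, and fry gave an upward direction (adjusted p = 0.0492; camera 0.325) that did not pass with RLE scaling or without scaling (fry adjusted p = 0.0965 and 0.103). Of 15 zinc finger genes ZNF292 rose (41.8 to 93.4 CPM) and 3 fell (ZNF775, ZNF628 and ZNF444), ZNF444 not passing without scaling (adjusted p = 0.0571), while adjusted over the list alone 7 rose and 5 fell. Their median log2 fold change was 0.58 and their mean 0.25. Of 17 mitochondrial proteins PINK1 and ABCB8 fell (-0.53 and -0.85), and of 15 cytoskeleton genes CHN2 rose (1.11) and the actin-bundling PALLD fell (-0.95). SEPHS2 (0.48) was the 1 of 9 redox genes to pass. Adjusted over the list alone, 0 rose and 0 fell in each of these 3 lists. Of 7 cilia genes none passed (camera adjusted p = 0.508), with IFT80 at 0.995 ± 0.397 and TSPAN19 at 2.10 ± 0.92, and none of 9 leukocyte genes passed. H19 (102 CPM, SD 48.7, and 77.1 CPM, SD 30) and MEG3 (156 CPM, SD 40.7, and 113 CPM, SD 31.2) did not pass, MEG3 passing with limma-voom (adjusted p = 0.00476). Over the imprinted list of XIST, MEG3 and H19 1 rose, also adjusted over the list alone, with a median of -0.40, a mean of 0.01 and a downward direction by camera (adjusted p = 0.888). In total 3353 of 14542 genes (23.1%) passed, 1479 higher and 1874 lower in SCNT, and of 227 named genes 20 were higher and 25 lower. The smallest adjusted p of any gene was 0.0409, and 148 genes (1.02%, where chance gives 0.253%) had groups that did not overlap.

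This count changed widely with 1 library left out. The smallest adjusted p with all libraries, 0.0409, lay close to the threshold. A lost call alone therefore does not show that the effect rested on that library. No gene passed without SCNT library 61, 67 or 71 or without AI library 77, 81 or 91, 1 gene passed without SCNT library 57, 26 without SCNT library 63 and 1199 without AI library 83, where 6944 genes had an unadjusted p under 0.05 with all libraries, while 6853 passed without SCNT library 69 and 7254 without AI library 85. Without the library of each group farthest from its mean 8898 passed. FAM229B, SMIM1, PLXNA3, ZNF775, ABCB8 and PALLD each passed in 4 of 12 such runs, those without SCNT library 65 or 69 or AI library 83 or 85, and kept their sign in all 12 (adjusted p up to 0.132). XIST, ERLIN1, GALNT4, TMEM167B, SFT2D2, RRM1, ZNF292, ZNF628, PINK1 and CHN2 passed in 3 of them, those without SCNT library 65 or 69 or AI library 85. SEPHS2 and ANAPC13 passed without SCNT library 69 or AI library 85, and ZNF444 without AI library 85 (adjusted p up to 0.149). With all libraries DESeq2 called 5988 and limma-voom 10273. The difference of the SCNT effect between caruncle and inter-caruncle endometrium at day 34 passed for 0 of 15254 genes (4804 at an unadjusted p under 0.05; DESeq2 1955, limma-voom 6920), with 3580 without inter-caruncle AI library 85, 2776 without caruncle SCNT library 64 and 1801 without caruncle AI library 90.

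The SCNT effect between caruncles differed between day 18 and day 34 for 4993 of 15281 genes, 1969 with a more positive and 3024 with a more negative effect at day 34. Limma-voom called 9876 genes and DESeq2 5941. Without scaling the split was 2526 and 2359, and the median over all genes moved by 0.11. In each of the 10 named genes with the smallest p the AI mean moved from day 18 to day 34 and the SCNT mean stayed nearer to its day 18 value. Whether the other called genes took this course was not counted. FAM229B went from 26.9 to 11.5 CPM in AI and from 24.0 to 22.4 CPM in SCNT pregnancies (interaction 1.14 ± 0.27, adjusted p = 0.0182), CHN2, a regulator of Rac, from 29.7 to 10.1 and from 24.5 to 21.5 CPM, and ERLIN1 from 217 to 114 and from 209 to 208 CPM. RABGAP1 and FGB took the same course (0.59 ± 0.17 and 1.76 ± 0.53). PALLD went from 31.2 to 107 CPM in AI and from 37.2 to 52.8 CPM in SCNT pregnancies (-1.27 ± 0.31), SPEG, a muscle kinase, went from 37.3 to 176 and from 39.7 to 74.6 CPM (-1.32 ± 0.35), and KLHL36 from 26.5 to 74.4 and from 32.2 to 37.1 CPM (-1.28 ± 0.29). INTS1, of the Integrator complex, whose counts were identical to those of a second identifier, and PPP1R1A, a phosphatase inhibitor, had interactions of -1.22 ± 0.31 and -2.28 ± 0.56. The count was 0 without day 34 AI library 81, 1757 without AI library 77, 2920 without SCNT library 71, 3195 without day 18 AI library 16 and 7843 without day 34 AI library 85 (7478 genes had an unadjusted p under 0.05 with all libraries). The 10 named genes lost their calls without AI library 81 (adjusted p between 0.0544 and 0.0621), RABGAP1 and ERLIN1 also without AI library 77. In caruncle the effect differed between the days for 4 of 15312 genes, none with a symbol. That count was 0 without day 18 AI library 9 or 17, without day 34 AI library 76 or 90 or without SCNT library 62, and 2 without day 34 AI library 82 or SCNT library 56. At the full set 1377 genes had an unadjusted p under 0.05 (chance gives 766), DESeq2 called 39 and limma-voom 870.

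Within AI pregnancies caruncle and inter-caruncle endometrium at day 18 differed for 2493 of 14646 genes, 1261 higher between caruncles and 1232 higher in caruncle. The imprinted RNAs H19 and MEG3 were higher in caruncle, at 368 against 97.6 CPM (log2 fold change -1.92 ± 0.30, adjusted p = 0.00609) and 224 against 94.9 CPM (-1.24 ± 0.24, adjusted p = 0.00977), as were SPEG (86.8 against 37.8 CPM), the small GTPase RAB34 (83.3 against 54.8 CPM) and ASXL3. CHN2 (30.1 against 17.5 CPM), ABHD3 (67.2 against 41.8 CPM), the glutamate receptor GRM7, C23H6orf52 and SMIM13 were higher between caruncles. The count was 1199 and 1264 without caruncle library 1 or 3, and 1265, 1361, 1356 and 1382 without inter-caruncle library 2, 4, 10 or 18. At day 34 the areas differed for 6 of 14326 genes, 3 in each direction and none with a symbol (3134 at an unadjusted p under 0.05; DESeq2 982, limma-voom 8720). With RLE scaling or none it was 3, 2 higher between caruncles and 1 in caruncle, and with no low-count filter 14. It was 2 without caruncle library 76, 1 without caruncle library 80 or 84 or inter-caruncle library 77, 81, 83 or 91, 524 without inter-caruncle library 85 and 692 without caruncle library 90. These counts leave the candidate pairs out of account. With the title numbers as a block far more genes differed at day 34, a number given with the processing. Deviations of the AI pairs at day 34 correlated with r of 0.2, 0.62, -0.02, 0.65 and 0.39.

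From day 18 to day 34 within AI pregnancies 2899 of 14586 genes changed in caruncle, 1544 higher and 1355 lower, and 9626 of 14504 between caruncles, 4916 higher and 4710 lower. Limma-voom called 6906 in caruncle and 11243 between caruncles, and DESeq2 3953 and 10043. FXYD5, a regulator of the sodium pump, rose in both areas (49.5 to 135 CPM in caruncle and 31.6 to 138 CPM between caruncles), as did PLXNA3 (27.4 to 64.5 and 22.1 to 77.8 CPM) and LDOC1 (7.57 to 24.8 and 3.11 to 22.4 CPM). KIF5C, a kinesin, fell in both (69.9 to 15.5 and 48.2 to 8.56 CPM), as did NUDT12 (77.9 to 15.6 and 132 to 17.4 CPM). PIN4 and SMIM1 rose and ATP5MK, RASGRF1 and CHMP1B fell in caruncle. C15H11orf96 (23.9 to 123 CPM) and ARHGAP1 rose between caruncles, and XIST (1610 to 566 CPM), ODR4 and ZNF292 (174 to 41.9 CPM) fell there. Log2 fold changes of these genes ranged from -2.93 to 2.87, with an adjusted p of at most 0.00703, and the counts of ODR4 were identical to those of a second identifier.

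Within AI pregnancies at day 34 chorion and allantois differed for 5677 of 13505 genes, 2808 higher in allantois and 2869 higher in chorion. HPCAL4, a calcium sensor (3.80 against 174 CPM; log2 fold change 5.53 ± 0.40, counts identical to those of a second identifier), the glutamate receptor subunit GRIK5 (0.0406 against 9.52 CPM), SERP2, FAM110B and the mitochondrial iron importer SLC25A37 (82.9 against 291 CPM) were higher in allantois. The potassium channel gene KCNJ12 (91.9 against 2.25 CPM; -5.34 ± 0.38), the transcription factor BHLHE41 (39.9 against 1.81 CPM), GALNT4 (319 against 25 CPM), LOC782781 and C5H12orf75 were higher in chorion. H19 was at 368 CPM in chorion and 654 CPM in allantois (0.83 ± 0.23, adjusted p = 0.0145). Without scaling the median over all genes moved by 0.14, with 3178 genes higher in allantois and 2441 in chorion.

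SCNT libraries were not more spread out than AI libraries in any set beyond the threshold of the permutation of distances to the group mean. The mean distance between SCNT libraries divided by that between AI libraries was 0.62 in extra-embryonic tissue (exact permutation p = 0.02, two-sided, adjusted p = 0.07 over the 7 sets) and 0.846 in day 18 caruncle (exact permutation p = 0.0185, adjusted p = 0.07), values below 1 meaning that AI libraries lay further apart. With the permutation planned beforehand both passed (adjusted p = 0.0245 for each). With the permutation of distances extra-embryonic tissue passed over the 1000 most abundant genes (0.47, adjusted p = 0.0245). With 1 library left out extra-embryonic tissue passed without AI library 9 (0.57, adjusted p = 0.0489, exact permutation) and day 18 caruncle without SCNT library 44 (0.816, adjusted p = 0.00544, exact permutation). In allantois it was 1.20 (adjusted p = 0.13), and in chorion 0.864, in day 18 inter-caruncle endometrium 1.22, in day 34 caruncle 1.05 and in day 34 inter-caruncle endometrium 0.90 (adjusted p between 0.492 and 0.691).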

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

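The test of the sex of the conceptus, the removal of each library's trend on exon length, the splits that part every pair, and the limma-voom runs for interactions were chosen only after results had been seen.

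In day 18 extra-embryonic tissue 5619 genes passed between SCNT and AI pregnancies, and 1 of 100 splits of the libraries, the real one, gave as many, with 2764 as the highest other, so that chance can be excluded. A trend of counts with exon length that differs between libraries is argued against as the whole cause, since 5555 genes passed with each library's trend removed. AI libraries that stand apart are a candidate explanation for much of the number, since 821 genes passed without AI library 20, 2721 without AI library 9 and 3622 without AI library 35, while 3741 passed without SCNT library 48. The number rose to 8375 without AI library 52. The sex of the conceptuses and the kind of pregnancy cannot be told apart, because the highest XIST value of an AI library, 29.78 CPM, lay below the lowest of the SCNT libraries, 95.68 CPM. An effect of nuclear transfer stays open, as untested.

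XIST was higher in every SCNT conceptus library than in every AI conceptus library. Maternal endometrium in the SCNT conceptus libraries is argued against, since the median share of their endometrium level that endometrium genes reached there was at most 0.0172 of the share that XIST reached. A difference in sex between the groups, which the labels do not give, and an effect of nuclear transfer on XIST stay open.

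In day 34 inter-caruncle endometrium 3353 genes passed, and 3 of 100 splits, the real one among them, gave as many. That share lies under the bar set beforehand, but the highest other gave 7467, which points to a structure of the samples. The share therefore does not exclude chance. The trend with exon length is argued against as the whole cause, since 3600 genes passed with it removed. An axis of variation between libraries that runs within both groups is a candidate explanation, since the absolute rank correlation across 3313 called genes of the fold change with the first component of group-centred day 34 caruncle libraries was 0.89, genes not being independent replicates. The number was 0 without SCNT library 61, 67 or 71 or AI library 77, 81 or 91, 1 without SCNT library 57, 26 without SCNT library 63, 1199 without AI library 83, 6853 without SCNT library 69 and 7254 without AI library 85. An effect of the cloned conceptus on the endometrium stays open, as untested.

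Of 88 groups of values checked for a library far from the others 2 held one (2.27%, where chance gives about 1 in 20). FAM174B was at 72.7 CPM in AI library 20 of day 18 extra-embryonic tissue, where the others lay between 4.58 and 17.7 CPM. XIST was at 7.56 CPM in AI library 4 of day 34 chorion, where the others lay between 0.7 and 2.55 CPM. Both use TMM-scaled library sizes.

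By interaction terms of edgeR the SCNT effect differed between the days for 4 genes in caruncle and for 4993 between caruncles, and between chorion and allantois for 1. The inter-caruncle interactions of the named genes, on the log2 scale, were 1.14 for FAM229B, 1.37 for CHN2, 0.59 for RABGAP1, 1.76 for FGB, 0.92 for ERLIN1, -1.28 for KLHL36, -2.28 for PPP1R1A, -1.27 for PALLD, -1.22 for INTS1 and -1.32 for SPEG. For the 4993 genes 1 of 100 splits, the real one, gave as many, under the bar set beforehand. The highest other, 3648, points to a structure of the samples, so that chance is not excluded there. The number of genes called was 0 without day 34 AI library 81. The test also draws on the day 34 inter-caruncle libraries, whose fold changes followed an axis of variation that runs within both groups. That axis was not tested for the interaction and stays a candidate explanation. Chance cannot be excluded for the 4 in caruncle (5 of 100, highest other 7442, a structure of the samples) or the 1 of chorion and allantois (5 of 100, highest other 2).

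Chance can be excluded for the 18 genes of chorion (1 of 100 splits, highest other 0). For the 7 of allantois 2 of 100 splits gave as many, under the bar set beforehand. The highest other, 154, many times the real number, points to a structure of the samples, so that chance is not excluded there. In both tissues sex and kind of pregnancy cannot be told apart. XIST reached at most 7.893 CPM in AI and at least 57.55 CPM in SCNT libraries of chorion. In allantois these values were 2.2 and 143.7 CPM. EdgeR called 0 genes in day 18 caruncle, day 18 inter-caruncle and day 34 caruncle endometrium and for the interactions of the areas at day 18 and at day 34, where 1197, 465, 1141, 393 and 4804 genes had an unadjusted p under 0.05 (chance gives 744, 744, 739, 767 and 763), DESeq2 called 5, 1, 123, 0 and 1955, and limma-voom 0, 0, 601, 0 and 6920. With 0 genes called every split gives at least as many, so that the share of splits cannot decide on chance there. The highest others, 11, 8, 5201, 308 and 7328, point at day 34 to a structure of the samples. Within AI pregnancies chance can be excluded for the days in caruncle (2899, 1 of 100, 615), the days between caruncles (9626, 1 of 100, 3581) and chorion against allantois (5677, 1 of 100, 4650). It cannot be excluded for the areas at day 34 (6 genes, 5 of 100), where the highest other, 7001, points to a structure of the samples. These splits were drawn without regard to the candidate pairs, and more genes passed with the title numbers as a block. The set of splits that part every pair was not run at day 34, so that the paired comparison was not tested by splits. For the areas at day 18 (2493 genes) 1 of 100 splits drawn without regard to the pairs, the real one, gave as many, and the highest other, 561, parted 3 of the 5 pairs. The splits that part all 5 pairs, as the real one does, number 16, too few for a share under 0.05. Their highest other was 0, against 2493 for the real one, and also 0 against 2359 with the pairs as a block.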

How the results depend on the processing

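Runs without scaling or with limma-voom for interactions and comparisons within AI pregnancies, runs without the library of each group farthest from its mean, with exon length trends removed or with identical counts kept once, and the permutation used for spread were chosen after seeing the data. Where a number below moved, the cause was not tested unless the alternative itself removed libraries or required a larger change. The libraries that decide single counts are named with the counts in the report.

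DESeq2 called 71 genes in chorion, 231 in allantois, 5 in day 18 caruncle, 1 in day 18 inter-caruncle, 123 in day 34 caruncle and 5988 in day 34 inter-caruncle endometrium. It called 1955 for the interaction of the areas at day 34, 39 for that of the days in caruncle, 17 for chorion against allantois and 982 for the areas at day 34 in AI pregnancies. Limma-voom called 72, 12, 601 (day 34 caruncle) and 10273 (day 34 inter-caruncle), for the interactions 6920 (areas at day 34), 870 (days in caruncle), 9876 (days between caruncles) and 22 (chorion and allantois), and in AI pregnancies 8720 (areas at day 34) and 6906 (days in caruncle). With 1 surrogate variable 54 genes passed in chorion and 1309 in day 34 caruncle. With XIST as a covariate 0 passed in extra-embryonic tissue and 0 in allantois, by edgeR, and 1 in chorion, a covariate that nearly repeats the group.

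Without scaling 3295 genes passed in extra-embryonic tissue, and 3 for the areas at day 34 in AI pregnancies, as with RLE scaling (3), while no low-count filter gave 14. Without the farthest libraries 3380 passed in extra-embryonic tissue, 4 in allantois and 8898 in day 34 inter-caruncle endometrium. With all libraries 1511 of the 3353 genes of day 34 inter-caruncle endometrium changed at least 2-fold. The imprinted list in day 18 caruncle turned its direction without scaling (camera of limma, adjusted p = 0.971), and H19 in allantois had a log2 fold change of -0.01. At a threshold of 0.01 extra-embryonic tissue shared 2 higher genes with chorion (one-sided Fisher's exact test, p = 0.000472) and 1 with allantois (one-sided Fisher's exact test, p = 0.00978). XIST was among those shared with chorion and was the only gene shared with allantois. The spread ratio of extra-embryonic tissue passed with the planned permutation (0.62, adjusted p = 0.0245) and over the 1000 most abundant genes (0.47, adjusted p = 0.0245), and that of day 18 caruncle with the planned permutation (0.846, adjusted p = 0.0245).

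With 1 library left out the numbers ranged from 821 to 8375 in extra-embryonic tissue, 9 to 20 in chorion, 2 to 87 in allantois, 0 to 12 in day 34 caruncle and 0 to 7254 in day 34 inter-caruncle endometrium. For the interactions they ranged from 0 to 3580 (areas at day 34), 0 to 6 (days in caruncle), 0 to 7843 (days between caruncles) and 0 to 2 (chorion and allantois), and in AI pregnancies from 1199 to 2916 (areas at day 18) and 1 to 692 (areas at day 34). Spread ratios ranged from 0.57 to 0.712 in extra-embryonic tissue, passing without AI library 9, 0.767 to 1.2 in chorion, which turned without AI library 4, 0.816 to 0.928 in day 18 caruncle, passing without SCNT library 44, 0.944 to 1.14 in day 34 caruncle, which turned without SCNT library 70 (0.946), AI library 76 (0.944) or AI library 84 (0.996), and 0.82 to 1.03 in day 34 inter-caruncle endometrium, which turned without AI library 85. H19 in allantois ranged from -0.05 to 0.17 and SLC25A37 in day 34 inter-caruncle endometrium from -0.02 to 0.13.

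With the title numbers as a block, 2359 genes differed between the areas at day 18 and 1378 at day 34 in AI pregnancies, and 0 passed for each interaction of the areas, as without the block by edgeR; it changed no other call. At day 34 the deviations of candidate pairs correlated by over 0.1 in 9 of 12 pairs (r from -0.61 to 0.65) and 6 of 12 caruncle libraries correlated best with their own partner, so that the numbers may only be shared there. The AI pairs, which alone enter the comparison of the areas in AI pregnancies, had r of 0.2, 0.62, -0.02, 0.65 and 0.39. Among these all caruncle libraries but 82 correlated best with their own partner.

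For 146 named genes under 4 alternatives each, 537 of 584 values kept their direction and side of the threshold, 10 no longer passed, 36 newly passed and 1 turned. In data simulated at the real depths and the spread of each gene 24% of genes changed 2-fold were recovered in extra-embryonic tissue, 14% in day 34 caruncle and 92% in day 18 caruncle, and depth itself was not varied. Genes were drawn independently and the changed ones were abundant, so that these rates do not cover factors shared between genes. Only 200 genes were changed, so that the rates do not describe sets in which many genes passed.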

Other observations

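The values of this part were chosen after they had been seen and were not tested.

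TKDP1, a Kunitz domain protein of the trophoblast, was above 10 CPM in 3 of 14 caruncle libraries and in 3 of 14 inter-caruncle libraries at day 18. The values in caruncle were 50.01 CPM in AI library 9, 193.3 CPM in SCNT library 38 and 48.02 CPM in SCNT library 44, the rest reaching at most 2.862 CPM. Between caruncles they were 34.98 CPM in AI library 10, 64.57 CPM in SCNT library 39 and 35.63 CPM in SCNT library 45, the rest reaching at most 0.5189 CPM. By title number these libraries form 3 pairs, 9 with 10, 38 with 39 and 44 with 45, and so are not separate occurrences if the numbers pair the samples. At day 34 none of 12 caruncle and none of 12 inter-caruncle libraries lay above 10 CPM, the highest being 6.879 and 2.349 CPM.

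Of 3313 genes called in day 34 inter-caruncle endometrium and tested in day 34 caruncle, 894 (27%) had a fold change of the same sign there. The fold changes of these genes followed 1 axis of variation between caruncle libraries (absolute rank correlation 0.89), so that their signs are not independent. The interaction of the areas at day 34 called 0 genes by edgeR.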
